A study of Mus musculus with 36 samples.

How the data were processed

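RNA was measured by sequencing polyadenylated RNA from bone marrow-derived macrophages of 6 mice, 3 with wild-type Cop1 and 3 with floxed Cop1, all with a Cre recombinase gene at Rosa26, each at 6 times, which gave 36 libraries in 12 groups of n = 3. RNA was purified on columns with DNase digestion, per the labels' protocols. Replicates came from separate individuals, per the labels, and the same 3 individuals of each genotype were sampled at every time.

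The deposited count table holds, per the file headers, the number of uniquely aligning reads for each Entrez gene model, not normalised. The deposited RPKM table holds, per the file headers, RPKM adjusted by size factors. Another deposited table gives, per the file headers, the size of each gene model and its symbol, an other kind of value used here for symbols only. The deposited table of each library repeats its counts and RPKM values from these tables, per the file headers and the values. Reads were aligned with GSNAP to GRCm38, per the submitters' processing notes; the versions, the annotation release and the strand setting were not given in the sources used here. Only uniquely aligning reads were counted, so near-identical gene copies can be undercounted, and without a known strand setting overlapping genes cannot be told apart. All columns of per-sample values were used, every row had a gene ID, and ribosomal RNA rows held 0.00861% of the counts. Of the 36528 gene IDs, 31049 (85.0%) matched the RefSeq table of GRCm38.p6, from which coordinates were taken, counted from 1. The symbol Rfwd2 in the table was read as Cop1.

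Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 12 groups, which left 15685 genes, libraries were scaled by TMM, and the quasi-likelihood test was applied to a model with 1 mean per group, so that all 36 libraries shared the estimates of spread. TMM factors were 1.53 to 1.73 in untreated libraries and 0.747 to 0.942 at T4 to T9. Contrasts were Cop1-floxed minus wild type at each time, each LPS time minus T0 in each genotype, and the difference of these responses between genotypes, tested with 1 F test over the 5 interaction terms. For the summed comparison the counts of the 6 libraries of each mouse were added, giving 3 sums per genotype and 17182 genes. The p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. The test of each comparison, the gene lists and the rule for named genes were fixed before the data were examined.

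The text names Cop1, and then the 10 genes with the largest rise and the 10 with the largest fall at T0 between genotypes, at T2.5 and T13 in wild-type cells with LPS and in the summed comparison, among genes that passed, with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. For genotype under LPS it names the 15 highest and 15 lowest mean log2 fold changes among genes that passed with the same sign at 3 or more LPS times, and for the interaction the 10 smallest F p-values with an interaction of at least 1 on the log2 scale. It also names up to 4 members of each list by adjusted p, and Cebpb, Cebpa, Cebpd, Jun, Ets2, Etv5, Trib1, Tnf, Il1b, Il6, Il10, Il12b, Nos2, Arg1, Ptgs2 and Ifnb1. Gene models without a proper name and pseudogenes were left out, and 1 gene that the rule names is not reported here. Some further members of the lists, such as Cxcl11, Mx2, Lif and Ccr7 at T0, were chosen as examples after their values were seen. Gene positions are given for a few key genes.

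The 28 tested gene lists were written from general knowledge; a list of sex-linked genes was used only to compare libraries. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, again with a correlation estimated for each list, and with fry, and adjusted over the 28 lists. No list that camera called had a median, mean and test of different signs. Of the 155 camera calls over all comparisons, 6 had a median that changed sign with library totals and 0 with the size factors of DESeq2. A fold against a group with 0 counts was set against a floor of 3 counts over the group.

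The alternatives tried were the size factors of DESeq2, no filter and a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-trend on log2(RPKM + 1) for genes with a mean RPKM of at least 0.1, limma-voom with a correlation within individuals (0.148), a block for the individual, a block for the replicate number, the 6 libraries of a time alone, the mean contrast over all libraries, and leaving out each individual. Alternatives added after seeing the data were library totals, leaving out the library Cop1-floxed T9 replicate 2 or wild type T0 replicate 2, the stromal list score as a covariate, and T0 on the 14344 genes that LPS induced under 10-fold.

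Pairing was checked as the correlation of deviations from the group means. For libraries of the same individual at different times, the 90 pairs had a median r across genes of 0.139 (from -0.0986 to 0.470, 59 over 0.1). Genes are not independent replicates, and the pairing of LPS with T0 rests on the labels, since the libraries came from the same mice.

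The tests were also run on simulated data, with counts drawn around the means and spread of the fit to the real libraries and 200 genes changed by known folds. The changed genes were drawn from those with a mean of at least 5 CPM, and each library was drawn separately. The recovery therefore does not cover genes with fewer reads, deviations shared by the libraries of a mouse, or a library that stands apart. For the genotype difference at T9, edgeR recovered 46 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold among 15515 genes, with 10 false calls. The interaction test recovered 15 of 67, 52 of 67 and 66 of 66 of the genes changed by these folds, with 7 false calls. Libraries held 24069541 to 40298009 counted reads. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 8.54 to 142. Errors of CPM are the SD between the mice of a group. Standard errors at single times use a spread shared over all 36 libraries, with the 6 libraries of a mouse counted as separate samples. Of the main comparisons, only the summed one takes the mouse as the unit.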

Results

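Polyadenylated RNA was sequenced from macrophages grown from mouse bone marrow and left untreated or treated with lipopolysaccharide (LPS), a bacterial outer membrane component that activates macrophages through the receptor TLR4. The cells came from 3 mice with a wild-type Cop1 gene and from 3 mice with a loxP-flanked Cop1 gene, called wild type and Cop1-floxed here. Both genotypes carried a tamoxifen-inducible Cre recombinase at the Rosa26 locus, and the series title describes the second as a Cop1 knockout. Cop1 encodes a ubiquitin ligase that marks transcription factors such as c-Jun, ETS family members and, together with Tribbles proteins, C/EBP proteins for degradation. Each of the 6 mice gave 6 libraries, 1 untreated at T0 and 5 with 100 ng/ml LPS, added at day 7 of differentiation, at T2.5, T4, T6, T9 and T13. This made 36 libraries, 3 from separate mice, per the labels, in each of the 12 groups. The libraries of wild-type replicate 2 held reads of both Xist and Y-linked genes, and whether they hold RNA of more than 1 mouse was not given in the sources used here. The unit of the time labels and whether the cells received tamoxifen were not given in the sources used here. Because all treated libraries carry a later time label than the untreated ones, LPS and time in culture were not separated.

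Library totals ranged from 24069541 counted reads (wild type T0, replicate 2) to 40298009 (wild type T13, replicate 1), with a median of 34549113. Of 36528 genes, 11057 had 0 counts in every library and 15685 entered the tests. The first principal component held 47.6% of the variance and the second 22.8%. No pair of replicates matched within sampling noise, since the chi-square per degree of freedom of the 36 pairs was at least 8.54. The library Cop1-floxed T9 replicate 2 detected 15045 genes, against 17622 to 19693 in the others. Unless stated otherwise, values are log2 fold changes or CPM scaled by edgeR's TMM, groups are n = 3, errors of CPM are SD, and p-values are adjusted values from edgeR's quasi-likelihood test.

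The first comparison asked whether the targeted gene itself differed between the genotypes. Cop1 (Entrez 26374; chromosome 1, 159232156 to 159354872 in GRCm38.p6) was lower in Cop1-floxed cells at every time. Untreated wild-type cells had 10.1 ± 0.267 CPM and untreated Cop1-floxed cells 6.21 ± 0.397 CPM, a log2 fold change of -0.70 (SE 0.115, adjusted p = 1.40e-04). Under LPS the difference lay between -1.21 at T2.5 (SE 0.118, adjusted p = 3.43e-07) and -0.77 at T6 (adjusted p = 1.10e-04). The lowest of the 18 wild-type libraries had 9.92 CPM and the highest of the 18 Cop1-floxed libraries 8.71 CPM (T6, replicate 2), so the genotypes did not overlap. Cop1 reads remained in every Cop1-floxed library. Which part of the gene is deleted was not given in the sources used here, so reads over the whole gene can include reads from a shortened transcript. The share of cells in which the gene was deleted was not given either, so the remaining reads can also come from undeleted cells, and each genotype effect is that of the whole culture. When only the 6 untreated libraries were fitted, the T0 difference was -0.76 with an adjusted p of 0.065.

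**Figure D1:**
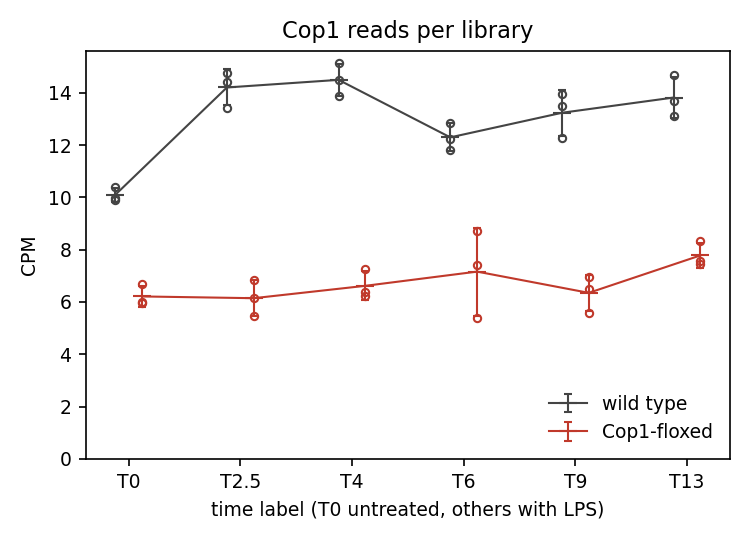
Cop1 level in CPM (vertical axis) by time label (T0 untreated, all others with LPS) in wild-type (grey) and Cop1-floxed (red) macrophages; circles are the 3 mice of each group, and bars the mean ± SD. Every Cop1-floxed library, at most 8.71 CPM, lay below every wild-type library, at least 9.92 CPM.

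The second comparison asked how wild-type macrophages responded to LPS. At T2.5, genes for cytokines, chemokines and interferon-induced proteins were among those that rose the most. Cxcl10, a chemokine that attracts T cells (chromosome 5, 92346638 to 92348889), went from 8.96 ± 5.07 to 5859 ± 425 CPM, a log2 fold change of 9.37. Ifnb1, which encodes interferon beta, rose by 10.24 (SE 0.485) to 89.8 ± 14.7 CPM. Il12b, encoding a subunit of interleukins 12 and 23, rose by 9.40, and Cxcl11, Rnd1, Tnfsf9 and Ccl4 rose by 8.94 to 9.21. Steap4, a metalloreductase, and Il33, an alarmin cytokine, had 0 untreated counts and were at least 626-fold and at least 377-fold higher, each set against a floor of 3 counts over the group. Sele, encoding E-selectin, had 3 untreated counts and a ratio of 851, with an exact Poisson interval from 291 to 4125; such intervals and floors cover counting error only.

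The genes that fell the most by T2.5 included the Wnt pathway gene Frat1 (-7.24), the cannabinoid receptor gene Cnr2 (-5.94) and the pro-apoptotic gene Bmf (-5.35). The chemokine receptor gene Cxcr4 fell by 4.91 on the log2 scale, to 9.58 ± 0.976 CPM. Cebpa, encoding the myeloid transcription factor C/EBP alpha, fell from 431 ± 36.1 to 24.2 ± 4.10 CPM (-4.16, adjusted p = 6.90e-19). Lpar6, Rhov, Usp2, Klhl21 and Dnajc28 fell by between 4.20 and 5.33 on the log2 scale.

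At T13, among the named genes with more than 3 untreated counts, the highest rises were in BC023105 (10.43), Cxcl11 (10.25) and Ccl12 (9.87). The endothelial lipase gene Lipg (9.67), Slfn4 (9.56) and the interferon-induced GTPase genes Gbp4 (9.19) and Tgtp1 (9.01) followed. Il1f6, an interleukin 1 family gene with 0 untreated counts, was at least 358-fold higher. Il23r, which encodes a subunit of the interleukin 23 receptor, had 2 untreated counts and a ratio of 2082 (exact Poisson interval 576 to 17190), and Heatr9 had 3 and a ratio of 839 (287 to 4069). Nptx1 (-8.65), the organic anion transporter gene Slco2b1 (-7.90) and Rasgrp3 (-6.02) fell the most. Amz1, Cxcr4, St6gal1, Nat8l, Gprc5c, Hpgd and Zfyve28 fell by between 4.95 and 5.94 on the log2 scale.

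Interferon-stimulated genes rose together: 34 of 34 measured members rose at each of the 5 times (also 34 adjusted over the list alone at T2.5 and T13), with a median of 5.51 at T2.5 and 6.84 at T13, and with Mx2 at 7.77 and Irgm1 at 4.63 at T2.5. Of 30 inflammatory cytokines and chemokines, 29 rose and 0 fell at T2.5 (29 adjusted over the list alone), among them Ccl2 (8.28), Ccl3 (7.56) and Tnf (7.07). Their median was 7.42, or 7.22 with the 1 member that had no untreated counts set to its bound. By T13, 25 had risen and 1 had fallen, with a median of 4.12. Feedback inhibitors of NF-kB and cytokine signalling rose in 21 of 22 members at T2.5 (Tnfaip3 6.43, Nfkbia 4.31) and in 20 at T13, with medians of 4.18 and 2.62. Genes of the C/EBP family and their reported targets rose in 22 of 28 members at T2.5 and in 24 at T13, while 1 and 2 fell, with medians of 2.40 and 3.18. Pattern recognition and inflammasome genes rose in 18 of 26 members at T2.5 and in 21 at T13, while 3 and 4 fell (Nod2 5.66, Casp4 3.73 at T2.5). These 5 lists were called by camera at every time, and all 5 also passed with an estimated correlation, the largest adjusted p with an estimated correlation being 0.0399 for the cytokines at T13.

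Genes of antigen presentation by MHC class I rose in 15 of 15 members at every time, with a median of 1.29 at T2.5 and 2.93 at T13 (Tap1 3.11 and 4.27). Camera called this list at every time (T2.5, adjusted p = 1.15e-06), but at T2.5 it had an adjusted p = 0.222 with an estimated correlation, against 0.0099 at T13. AP-1 family genes rose in 12 of 15 members at T2.5 (Batf2 5.56; median 1.84), where the call passed with an estimated correlation (adjusted p = 0.0081). At T13, 7 of the 15 rose and 4 fell, and camera did not call the list (adjusted p = 0.057). Extracellular protease and coagulation genes rose in 14 of 23 members at T2.5 and 16 at T13, with 2 and 4 falling; both camera calls were lost (adjusted p = 0.050 and 0.218 with an estimated correlation). Dendritic cell markers rose in 12 of 15 members at T2.5 (camera adjusted p = 0.041), with an adjusted p = 0.723 with an estimated correlation.

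At T13, 22 of 27 genes of sterol and fatty acid synthesis fell and 1 rose, with a median of -1.30 (Fasn -2.68, Stard4 -2.28, Fads1 -2.06, Sqle -1.79; camera adjusted p = 2.13e-07). The list had an adjusted p = 0.056 with an estimated correlation. Of 30 cell cycle genes, 24 fell and 3 rose at T13, with a median of -1.27 (Cdc20 -3.12, Top2a -2.18, but Ccnd1 1.58); this call was also lost (adjusted p = 0.554 with an estimated correlation). Glycolysis and HIF-1 target genes rose in 20 of 24 members (median 1.17) and heat shock genes in 10 of 14 (median 1.10) at T13, with an adjusted p = 0.138 and an adjusted p = 0.268 with an estimated correlation. At T13 camera did not call the macrophage identity markers (9 rose and 11 fell of 24), lysosome genes (10 and 14 of 30), genes of the unfolded protein response (14 and 3 of 23), NRF2 targets (6 and 10 of 17), LXR targets (2 and 6 of 11), p53 targets (6 and 9 of 19), eicosanoid genes (7 and 8 of 16), or alternative activation markers (5 and 7 of 13). For 4 of these 8, the macrophage, lysosome, eicosanoid and alternative activation lists, the median and the mean differed in sign.

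In all, edgeR called 9228 genes at T2.5 (4515 higher, 4713 lower), 10647 at T4 (4940 and 5707), 11059 at T6 (5034 and 6025), 10999 at T9 (5059 and 5940) and 10555 at T13 (5114 and 5441). At least 2-fold changes numbered 2435 higher and 2254 lower at T2.5, and 2800 and 2926 at T13. Scaling by library totals moved the median of all genes to -0.72 at T2.5, -1.10 at T6 and -0.80 at T13, and the splits to 2324 higher and 9700 lower, 2504 and 10529, 2592 and 10737, 2705 and 10480, and 2587 and 10002. Directions are therefore relative to the TMM scaling, under which the medians were between -0.15 and -0.06.

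The same comparison in Cop1-floxed cells called 8942 genes at T2.5 (4551 higher, 4391 lower), 10468 at T4 (4968 and 5500), 11031 at T6 (5111 and 5920), 11120 at T9 (5093 and 6027) and 10324 at T13 (4830 and 5494). With library totals the splits were 2278 and 9269, 2412 and 10428, 2456 and 10880, 2596 and 10635, and 2664 and 9640. All 34 interferon-stimulated genes rose at T2.5 (median 4.78) and at T13 (5.54). Of the 30 cytokines and chemokines, 30 rose at T2.5 (median 6.20) and 26 at T13 (3.53). Sterol and fatty acid synthesis genes fell in 23 of 27 members at T13, with a median of -1.78 (adjusted p = 0.033 with an estimated correlation). Whether the response differed between genotypes was tested directly by the interaction terms.

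**Figure D2:**
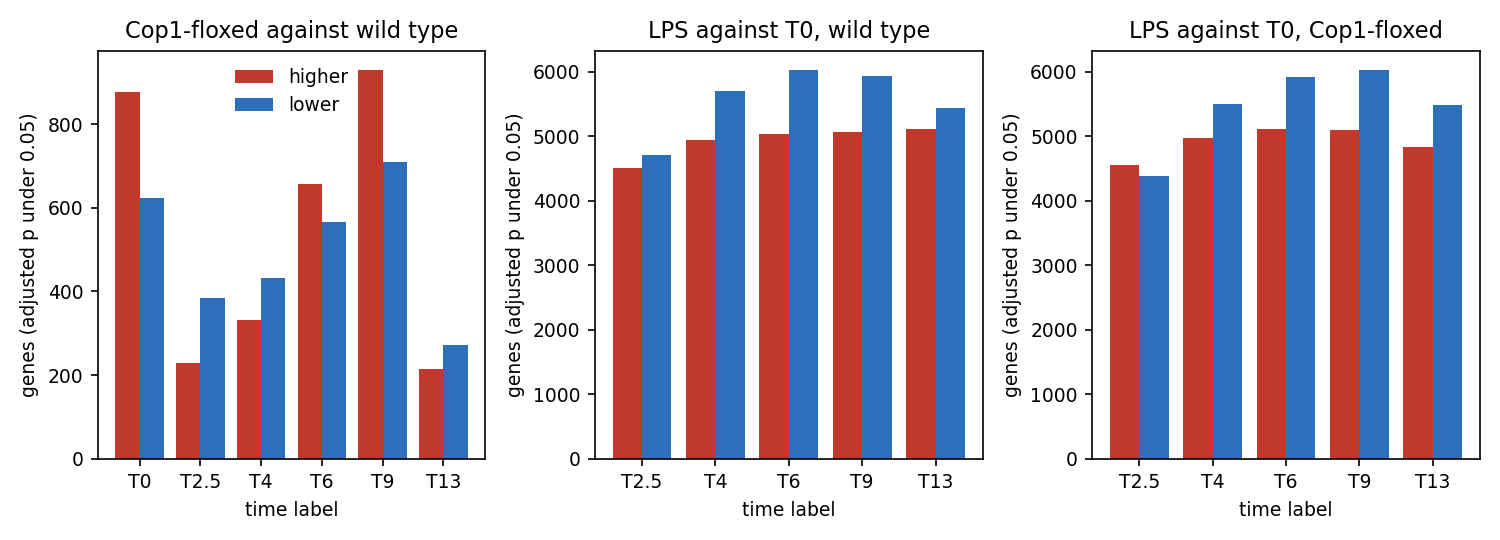
Number of genes with an adjusted p under 0.05 (vertical axis) by time label for the genotype difference (left), LPS against T0 in wild-type cells (middle) and LPS against T0 in Cop1-floxed cells (right); red bars count higher genes and blue bars lower genes, n = 3 per group. The genotype difference had 1501 genes at T0, 486 at T13 and 1639 at T9, and LPS between 8942 and 11120.

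The third comparison asked how the genotypes differed before LPS. Untreated Cop1-floxed cells had higher levels of genes that LPS and interferon induce. Cxcl10 had 8.96 ± 5.07 CPM in wild-type and 46.2 ± 28.2 CPM in Cop1-floxed cells (2.38, SE 0.312, adjusted p = 7.31e-06). Rsad2, encoding the antiviral protein viperin, had 29.2 ± 6.80 and 90.6 ± 36.7 CPM (1.64, adjusted p = 1.75e-06), and Irg1, which encodes the enzyme that makes itaconate, 17.6 ± 6.56 and 60.5 ± 23.4 CPM (1.78, adjusted p = 6.54e-07). The activation marker gene Cd69 (from 1.45 ± 0.622 to 8.02 ± 5.24 CPM), Il1a (1.85), Ccl4 (1.76), Gbp5 (1.75), Cmpk2 (1.73), Ifi205 (1.68) and the collagenase gene Mmp13 (1.63) were the other 7 of the 10 genes named by the size of their rise. Among the genes fixed in advance, Il6 rose by 2.54 from 0.436 ± 0.151 to 2.47 ± 1.78 CPM, Il12b by 2.31, Il1b by 1.56, the Tribbles gene Trib1 by 0.98 and Tnf by 0.79, Nos2 also rose (adjusted p = 0.00899), and the ETS family gene Etv5 fell by 1.10 on the log2 scale. Cebpb (-0.24, adjusted p = 0.314), Cebpa, Cebpd, Jun, Ets2 (-0.32, adjusted p = 0.068), Il10, Arg1, Ptgs2 and Ifnb1 (1.42, adjusted p = 0.39) did not pass. Ets2 stayed short of the threshold in 13 of 18 alternatives. It passed in the others, among them edgeR without the library Cop1-floxed T9 replicate 2 (adjusted p = 0.044). Ptgs2 stayed short of it in 17 of 18. Of the genes that passed, Nos2 kept its call in 12 of 18 alternatives, Tnf in 13, Il12b in 14, Il1b in 15 and Il6 in 16. Trib1 and Etv5 each kept theirs in 17 of 19.

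The genes lowest in untreated Cop1-floxed cells included the collagen genes Col1a1 and Col2a1. Col1a1, encoding a chain of collagen I (chromosome 11, 94936224 to 94953042), had 172 ± 76.8 CPM in wild-type and 32.3 ± 7.68 CPM in Cop1-floxed cells (-2.41, SE 0.389, adjusted p = 1.11e-04). Timp3, an inhibitor of metalloproteinases (chromosome 10, 86300412 to 86349505), had 117 ± 45.9 and 22.8 ± 5.92 CPM (-2.36, adjusted p = 3.99e-04). The cartilage collagen gene Col2a1 (-3.55), the collagen-binding integrin gene Itga11 (-2.49), Prss23 (-2.47), Dkk3 (-2.37) and the smooth muscle actin gene Actg2 (-2.29) also fell. So did Mpo, encoding the granule enzyme myeloperoxidase, from 18.3 ± 17.6 to 0.988 ± 0.393 CPM (-4.20, SE 1.06, adjusted p = 0.0089), and Plac8 (-2.77). Without the untreated wild-type replicate 2, Mpo was at -3.17 with an adjusted p of 0.063.

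Of 34 interferon-stimulated genes, 29 rose and 0 fell at T0 (29 adjusted over the list alone; median 0.72), among them Cxcl11 (2.47), Ifit1 (1.44), Mx2 (1.17) and Ifit2 (1.11). Camera gave an adjusted p of 1.94e-43, and this was the 1 list at T0 that passed with an estimated correlation (adjusted p = 0.012). Of 30 cytokines and chemokines, 12 rose and 2 fell (14 and 3 adjusted over the list alone; median 0.63); Ccl2 rose by 1.53, while Csf1 (-1.40) and Lif (-1.65), growth factors made by many cell types, fell (without the untreated wild-type replicate 2, Lif had an adjusted p of 0.057). C/EBP family and target genes rose in 11 of 28 members (12 adjusted over the list alone; median 0.35), where 21 of the 28 are also held by another list, with the formyl peptide receptor genes Fpr1 (1.32) and Fpr2 (1.18) among them. Feedback inhibitors rose in 11 of 22 members and fell in 1 (median 0.35; Socs3 1.08, Tnfaip3 0.83, Il1rn 0.78). Camera called these 3 lists (adjusted p = 3.99e-07, 2.41e-07 and 1.37e-04), with an adjusted p = 0.156, 0.055 and 0.147 with an estimated correlation. Without the untreated wild-type replicate 2 the C/EBP list had an adjusted p = 0.0036 with an estimated correlation, 15 cytokines rose and 1 fell, and 7 feedback inhibitors rose and 0 fell. Pattern recognition genes rose in 6 of 26 members (Tlr7 0.81, Nlrp3 0.80), lysosome genes in 8 of 30 (Ctsl 0.72, Ctss 0.27) and macrophage identity markers in 5 of 24 (Itgam 0.51, Lyz2 0.47), with none falling. Their camera calls (adjusted p = 1.98e-04, 5.80e-04 and 0.018) had an adjusted p = 0.147, 0.280 and 0.147 with an estimated correlation; without that replicate 4, 6 and 5 members rose.

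Markers of stromal and endothelial cells fell in 10 of 14 members at T0 and rose in 0 (11 adjusted over the list alone), with a median of -1.42 (Postn -2.08, Acta2 -2.07, Pdgfrb -1.48, Pecam1 -1.22). Camera gave an adjusted p of 1.27e-15, and the list had an adjusted p = 0.055 with an estimated correlation. This marker shift stood beside the rise of the interferon, cytokine and C/EBP lists in the same libraries. Dendritic cell markers fell in 4 of 15 members (Ccr7 -2.62, Fscn1 -1.74, H2-Ab1 -0.89), lymphocyte markers in 1 of 6 (Ebf1 -1.96) and erythroid and platelet markers in 1 of 5 (Gp1bb -1.89). Camera called all 3 (adjusted p = 2.27e-05, 0.016 and 0.0039), with an adjusted p = 0.147, 0.108 and 0.147 with an estimated correlation. Without the untreated wild-type replicate 2 Fscn1 was the 1 dendritic cell marker that still passed (Ccr7 -2.63, adjusted p = 0.068; H2-Ab1 -0.61, 0.196; H2-Eb1 -0.56, 0.248), and Gp1bb did not pass (-1.24, 0.063). Reported Cop1 substrates fell in 2 of 15 members, the ETS genes Etv4 (-2.32) and Etv5, and rose in 0 (camera adjusted p = 0.0027; adjusted p = 0.126 with an estimated correlation).

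The other lists were not called by camera at T0. Of 19 neutrophil and granulocyte precursor markers, 4 fell (Mpo, Ctsg -3.77, Elane -3.38, Prtn3 -3.18) and 1, the neutrophil collagenase gene Mmp8, rose by 1.40 (adjusted p = 5.40e-09), from 17.7 ± 3.85 to 46.8 ± 3.96 CPM. Without the untreated wild-type replicate 2 none of the 4 passed (Ctsg -2.54, adjusted p = 0.106; Elane -1.94, 0.233; Prtn3 -1.81, 0.126), nor did Prss34 (-3.20, 0.124) or Nlrc5 (0.51, 0.127), which follow, Mmp8 did (1.26), and camera called glycolysis and MHC class I genes higher (adjusted p = 0.040 and 5.43e-06; adjusted p = 0.402 and 0.194 with an estimated correlation). Rises and falls numbered 2 and 1 of 10 for Cop1 ligase parts and Tribbles genes, 2 and 2 of 15 for AP-1 genes, 0 and 1 of 13 for alternative activation markers, and 0 and 1 of 6 for mast cell markers (Prss34 -3.93). They were 0 and 0 of 30 for the cell cycle, where edgeR gave no call over the list alone either, 2 and 3 of 19 for p53 targets, 3 and 1 of 24 for glycolysis, 0 and 1 of 27 for sterol synthesis (Scd1 -0.96), 1 and 0 of 11 for LXR targets and 1 and 0 of 17 for NRF2 targets. They were 1 and 2 of 23 for the unfolded protein response (median 0.006, mean -0.07), 1 and 1 of 14 for heat shock, 6 and 7 of 23 for proteases (median 0.20, mean -0.06), 4 and 1 of 16 for eicosanoids and 1 and 0 of 15 for MHC class I, where Nlrc5 rose by 0.72. Without the untreated wild-type replicate 2 they were 2 and 0 for the cell cycle (Mcm6 0.38, adjusted p = 0.033; Pcna 0.39, 0.012), 5 and 0 for MHC class I (H2-K1, B2m, Tap1, H2-T23 and Psme2), 1 and 1 for Cop1 ligase parts and Tribbles genes, 2 and 1 for AP-1 genes, 0 and 3 for p53 targets, 2 and 1 for glycolysis, 1 and 1 for LXR targets, 2 and 0 for NRF2 targets, 3 and 1 for the unfolded protein response, 7 and 6 for proteases and 3 and 0 for eicosanoids.

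At T0 edgeR called 1501 genes, 878 higher and 623 lower, of which 120 and 478 changed at least 2-fold. With library totals the split was 380 higher and 791 lower, while the median of all genes lay at -0.08. When only the 6 untreated libraries were fitted, edgeR called 9 genes (1611 with an unadjusted p under 0.05).

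The fourth comparison asked how the genotypes differed under LPS. Trem1, a receptor that amplifies inflammatory signals in myeloid cells (chromosome 17, 48232713 to 48246927), was higher by 0.99, 1.14, 1.20, 1.33 and 1.74 from T2.5 to T13, and at T13 had 13.1 ± 1.13 CPM in wild-type and 43.7 ± 6.84 CPM in Cop1-floxed cells (SE 0.228, adjusted p = 3.17e-05). Csf3, encoding the granulocyte growth factor G-CSF (chromosome 11, 98700183 to 98703631), was higher by 1.68 at T6 (SE 0.198, adjusted p = 4.01e-06; 26.2 ± 3.66 and 83.7 ± 18.6 CPM) and by 1.96 at T9 (SE 0.206, adjusted p = 2.95e-07; means 9.36 and 36.4 CPM). Ifitm6, an interferon-induced transmembrane family gene (chromosome 7, 141015812 to 141016892), had the highest mean over the 5 times, with values between 1.05 at T13 and 1.78 at T2.5, and lay at 1.79 before LPS. Filip1 (mean 1.26), Mcemp1 (1.25, but at T9 0.86 with an adjusted p of 0.050 that passed in 2 of 17 alternatives), Prokr1 (1.24), the integrin gene Itgb7 (1.21), the serotonin receptor gene Htr2b (1.11), Rhov (1.07), Bst1 (1.05), Map3k9 (1.04), Sh2d3c (1.03), the protease inhibitor gene Slpi (1.02) and the prostacyclin receptor gene Ptgir (0.98) followed. Mir7678 (1.05) lies inside Slpi in the annotation, so its reads are uncertain. Without the library Cop1-floxed T9 replicate 2, Filip1 (adjusted p = 0.054), Mcemp1 (0.117) and Map3k9 (0.093) did not pass at T9.

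**Figure D3:**
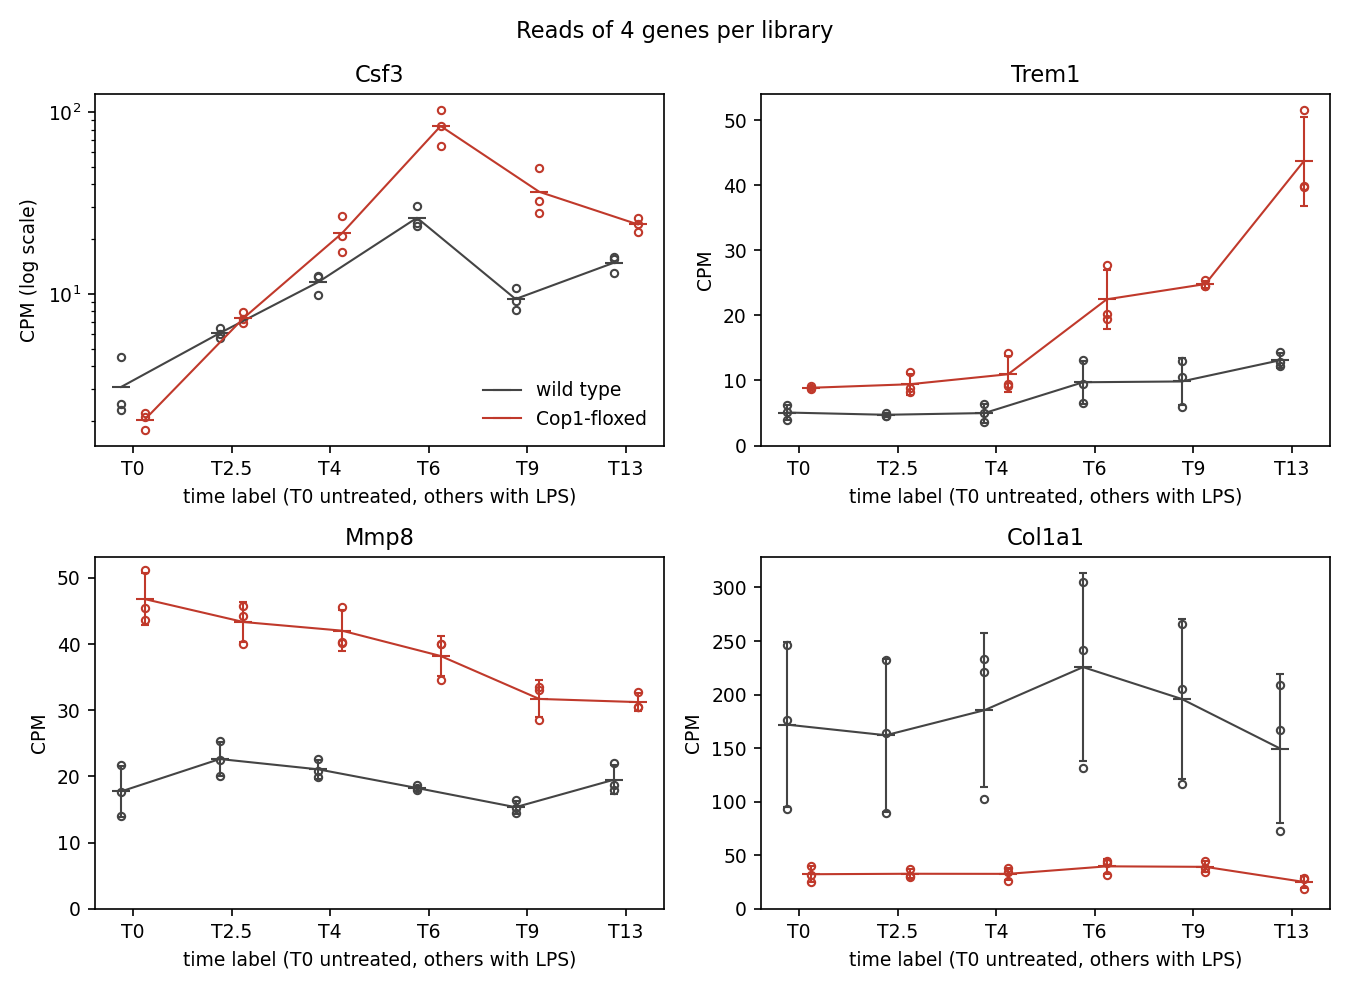
Levels of Csf3, Trem1, Mmp8 and Col1a1 in CPM (vertical axes, logarithmic for Csf3) by time label (T0 untreated, all others with LPS) in wild-type (grey) and Cop1-floxed (red) macrophages; circles are the 3 mice of each group, horizontal ticks the means, joined by lines, and bars the SD (not drawn for Csf3). Csf3 was higher in Cop1-floxed cells from T4 to T13, the most at T9 (9.36 and 36.4 CPM), and Trem1 at all 5 LPS times, the most at T13 (13.1 and 43.7 CPM), while Col1a1 was lower in Cop1-floxed cells at every time.

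The genes lowest in Cop1-floxed cells under LPS included Col1a1 and Postn, the 2 of the 15 that the stromal list holds. Col1a1 had 226 ± 87.8 CPM in wild-type and 39.7 ± 6.96 CPM in Cop1-floxed cells at T6, with a mean of -2.44 over the 5 times. Postn, encoding the matrix protein periostin (chromosome 3, 54359267 to 54391041), was at -2.37 at T9 (SE 0.278, adjusted p = 1.67e-06). The means were -3.45 for Col2a1, -2.76 for Prss23, -2.42 for Itga11 and -2.41 for Timp3, and between -2.35 and -2.12 for Thbs2, Wisp1, Lgr6, Dkk3, Actg2, Dclk1, Lrrc32 and Sulf1; Dkk3 at T9 did not pass without Cop1-floxed T9 replicate 2 (-2.04, adjusted p = 0.076).

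Stromal and endothelial markers fell in 11, 11, 9, 9 and 8 of 14 members from T2.5 to T13 (12, 14, 10, 11 and 10 adjusted over the list alone), with medians of -1.46, -1.68, -1.62, -1.56 and -1.38. Camera called the list at all 5 times, and it had an adjusted p = 0.019, 0.022, 0.074, 0.110 and 0.046 with an estimated correlation. It was the 1 list called for the genotype under LPS with an estimated correlation, at T2.5, T4 and T13. Its fall stood beside the changes of every other list under LPS. Lymphocyte markers fell in 1 of 6 members at T2.5, T4, T9 and T13 (Ebf1 -2.38 at T9), and the camera calls had an adjusted p = 0.186, 0.148, 0.149 and 0.075 with an estimated correlation. Dendritic cell markers fell in 1, 1 and 3 of 15 members at T2.5, T4 and T6, with an adjusted p = 0.186, 0.320 and 0.430 with an estimated correlation.

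The interferon-stimulated genes, higher in untreated Cop1-floxed cells, lay near equality under LPS: 0, 0, 1, 1 and 0 of 34 rose from T2.5 to T13 (Isg20 0.44 at T6 and 0.48 at T9). Their medians were -0.004, 0.02, 0.19, 0.15 and -0.05, and with library totals those at T6 and T9 were -0.01 and -0.02. Camera called them at T6 and T9 (adjusted p = 0.0017 and 0.039), with an adjusted p = 0.504 and 0.715 with an estimated correlation. C/EBP family and target genes rose in 3, 2, 9, 8 and 4 of 28 members, with Lcn2 at 1.53, Trem1 at 1.33, Ccl2 at 1.25 and Il10 at 0.88 at T9, while Il12b fell by 1.12 on the log2 scale; the members that fell numbered 1, 1, 0, 1 and 0. The list medians were 0.17, 0.26, 0.40, 0.36 and 0.15, and the camera calls had an adjusted p = 0.379, 0.471, 0.074, 0.110 and 0.144 with an estimated correlation. Lysosome genes rose in 3, 5, 11, 12 and 1 of 30 members (5, 12, 18, 18 and 1 adjusted over the list alone; Ctsl 0.72 at T9; 6 at T9 without Cop1-floxed T9 replicate 2), with medians up to 0.24 at T9 and an adjusted p = 0.225, 0.214, 0.076, 0.110 and 0.432 with an estimated correlation.

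Sterol and fatty acid synthesis genes fell in 5, 9 and 5 of 27 members at T6, T9 and T13 and rose in 0 (10, 14 and 9 adjusted over the list alone), with medians of -0.31, -0.48 and -0.28. At T9 Fasn was at -1.14, Stard4 at -0.81, Hmgcs1 at -0.62 and Sqle at -0.54. The camera calls (adjusted p = 1.64e-07, 2.34e-10 and 4.84e-09) had an adjusted p = 0.076, 0.086 and 0.075 with an estimated correlation. Cell cycle genes fell in 5 and 8 of 30 members at T6 and T9 and rose in 2 and 1 (Rrm2 -1.20, Aurkb -1.15, Top2a -0.86 at T9), with an adjusted p = 0.430 and 0.453 with an estimated correlation. The library Cop1-floxed T9 replicate 2 had the lowest mean log2 CPM of its group for both lists (2.99 for sterol synthesis and 1.41 for the cell cycle); without it 7 and 2 members fell at T9, 0 rose, Rrm2 did not pass (-0.96, adjusted p = 0.137), and camera still called both lists (adjusted p = 7.90e-09 and 3.36e-04; adjusted p = 0.059 and 0.464 with an estimated correlation). Without it 3 macrophage identity markers, 5 feedback inhibitors, 1 eicosanoid gene (Ptgir) and 0 MHC class I and 0 pattern recognition genes rose at T9, and camera no longer called lymphocyte, eicosanoid and pattern recognition genes at T9 (adjusted p = 0.115, 0.134 and 0.115), and newly called cytokines and proteases higher and NRF2 targets lower (adjusted p = 0.0063, 0.0073 and 0.021; adjusted p = 0.515, 0.332 and 0.515 with an estimated correlation). Macrophage identity markers rose in 6 and 7 of 24 members, feedback inhibitors in 3 and 6 of 22, MHC class I genes in 2 and 3 of 15 and eicosanoid genes in 2 and 3 of 16 at T6 and T9. These calls were lost, with an adjusted p = 0.076 and 0.110, 0.271 and 0.131, 0.430 and 0.453, and 0.193 and 0.163 with an estimated correlation. For MHC class I and pattern recognition genes the T6 median, 0.19 for both, was just below 0 with library totals. Pattern recognition genes rose in 2 of 26 members and fell in 1 at T6, and rose in 2 at T9 (adjusted p = 0.430 and 0.535 with an estimated correlation).

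Of 30 cytokines and chemokines, 0, 1, 8, 7 and 4 rose and 3, 4, 2, 5 and 0 fell from T2.5 to T13; without Cop1-floxed T9 replicate 2, 8 rose and 2 fell at T9 (Cxcl5 and Ccl22), as Il12a, Il12b and Lif did not pass (adjusted p = 0.081, 0.079 and 0.085). Camera called the list lower at T2.5 and higher at T13 (adjusted p = 0.037 and 0.0063), with an adjusted p = 0.714 and 0.627 with an estimated correlation. Macrophage identity markers at T2.5 and T4 (2 and 2 of 24 rose), erythroid and platelet markers at T2.5 (0 of 5 fell in edgeR), eicosanoid genes at T13 (2 of 16 rose) and glycolysis genes at T13 (0 of 24 rose, 1 fell) were also called. They had an adjusted p = 0.186, 0.320, 0.379, 0.075 and 0.383 with an estimated correlation. Neutrophil and granulocyte precursor markers, of which 1, 1, 5, 3 and 3 of 19 rose and 1, 2, 1, 1 and 1 fell (0 at T9 without Cop1-floxed T9 replicate 2), and reported Cop1 substrates, of which at most 1 of 15 rose or fell, were not called; the neutrophil list had a median of 0.20 and a mean of -0.34 at T9, and of 0.28 and -0.34 at T13.

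**Figure D4:**
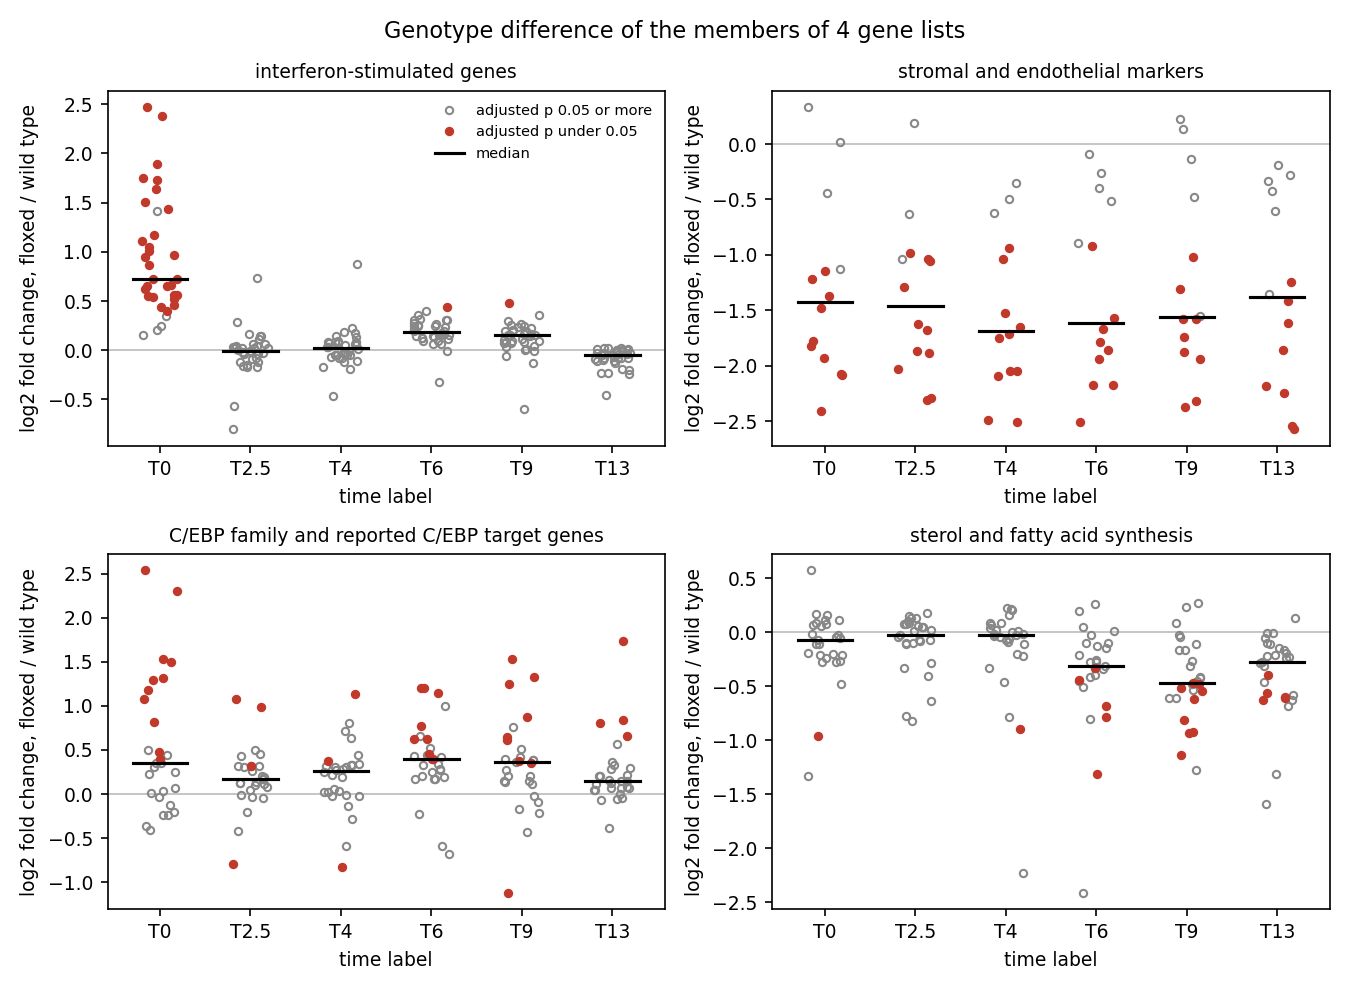
Log2 fold change, Cop1-floxed over wild type (vertical axes), by time label for the members of 4 gene lists; each point is a gene, filled where its adjusted p was under 0.05, and each black bar is the list median, from 3 mice per group. The interferon-stimulated genes had a median of 0.72 at T0 and between -0.05 and 0.19 under LPS, while the stromal and endothelial markers lay between -1.68 and -1.38 at all 6 times.

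Among the genes fixed in advance, Trib1 was higher at T2.5, T6 and T9 (0.47, 0.45 and 0.52), Il10 at T6 and T9 (0.78 and 0.88), Jun at T9 (0.53) and Ets2 at T2.5 (0.41), and Etv5 was lower at T13 (-0.79). Without the library Cop1-floxed T9 replicate 2, Trib1 at T9 (adjusted p = 0.068) and Il12b at T9 (0.079) did not pass, and Cebpa did (-0.56, 0.029); without wild type T0 replicate 2, Cebpb at T9 passed (0.39, 0.0065). Cebpb (at most 0.39, T9, adjusted p = 0.065), Cebpa, Cebpd, Tnf, Il1b, Il6, Nos2, Arg1, Ptgs2 and Ifnb1 passed at 0 of the 5 times in edgeR, where the counts of all genes at an unadjusted p under 0.05 were 1945 to 3778 per time.

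The calls numbered 612 at T2.5 (228 higher, 384 lower), 763 at T4 (331 and 432), 1224 at T6 (657 and 567), 1639 at T9 (929 and 710) and 486 at T13 (215 and 271). Across times, 261 genes were higher and 354 lower at 3 or more of the 5 LPS times, and 34 and 124 at all 5. With library totals the splits at T2.5, T4, T6 and T9 were 91 and 453, 100 and 544, 127 and 1093, and 244 and 1451, with medians of all genes down to -0.15. With the size factors of DESeq2, T2.5 had 162 higher and 435 lower, T4 210 and 494, and T6 466 and 603. Without the library Cop1-floxed T9 replicate 2, T9 had 783 calls, and without the library wild type T0 replicate 2, T2.5, T4 and T6 had 939, 1227 and 1894.

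The fifth comparison asked whether the LPS response itself differed between the genotypes, by a test of the 5 interaction terms together; all 5 share the untreated libraries. Positive values mean a stronger rise, or a weaker fall, in Cop1-floxed cells. The rise of Csf3 was larger in Cop1-floxed cells by 2.53 at T9 (SE 0.311, adjusted p = 6.24e-05). The antiviral genes Cmpk2 (-1.82, adjusted p = 5.30e-04), Ifit1 (-1.48) and Ifit2 (-1.29) at T2.5 and Rsad2 (-1.67) at T13 rose less, having started higher at T0. Sirpb1a, a signal regulatory protein gene, was at -1.35 at T13 (adjusted p = 3.22e-04), after a T0 difference of 1.43. The interaction was 2.63 at T4 for the matrix gene Tnn (SE 0.299, adjusted p = 1.25e-05), which at T0 differed by -2.36, 2.04 at T13 for Glipr2 (SE 0.298), 1.81 at T6 for Phlda1, and 1.13 at T9 for the growth factor gene Pdgfa. The test called 94 genes (1192 with an unadjusted p under 0.05), and 335 with the mouse as a block; without Cop1-floxed replicate 2 it called 14. Single times had 64, 56, 39, 133 and 115 calls from T2.5 to T13, of which 57, 46, 27, 73 and 98 were negative.

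The last comparison asked which genes differed between genotypes over the whole course, on counts summed over the 6 libraries of each mouse, with n = 3 mice per genotype. Mmp8 (1.02, SE 0.0662, adjusted p = 0.0033), Csf3 (1.14, SE 0.0932, adjusted p = 0.0048), Trem1 (1.25, adjusted p = 0.0075) and Ifitm6 (1.26, adjusted p = 0.0091) rose in Cop1-floxed cells. Prokr1 (1.18), Ptgir (1.05), Htr2b (1.01), the peroxisomal transporter gene Abcd2 (1.00), Fam83f (0.98) and Itgb7 (0.94) rose as well. Mpo (-3.33, SE 0.282, adjusted p = 0.0048), Col1a1 (-2.49, SE 0.312, adjusted p = 0.0089) and Postn (-2.27, adjusted p = 0.0048) fell. Itga11 (-2.50), Timp3 (-2.46), Dkk3 (-2.33), Thbs2 (-2.30), Actg2 (-2.26) and Lrrc32 (-2.20) also fell. Dkk3 kept its call in 8 of 15 alternatives, Lrrc32 and Abcd2 in 10 of 15 and Actg2 in 10 of 14. Mmp8, Csf3, Trem1, Prokr1, Mpo and Postn kept theirs in all, and the other genes named here in 11 to 13. Cop1 was at -0.99 (adjusted p = 0.0036). Of 17182 genes tested, 1259 passed, 408 higher and 851 lower, of which 24 and 599 changed at least 2-fold; with library totals the split was 245 and 1028. The count rested on single mice: without Cop1-floxed replicates 1, 2 and 3 in turn it was 51, 127 and 345, and without wild-type replicate 3 it was 82.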

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

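The tests of stromal cells, carried-over material, granulocytes and scaling were chosen only after the results were seen, and those of scaling for the lower genes and of carry-over for weakly induced genes replaced earlier forms whose outcome was fixed by the direction of the shift or by how the genes had been picked; the counts over other splits of the samples were planned.

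The test of the 5 interaction terms found that the LPS response differed between genotypes for 94 genes, and 10 of them were named by rule. These were Tnn (2.63 at T4), Csf3 (2.53 at T9), Sirpb1a (-1.35 at T13), Glipr2 (2.04 at T13), Pdgfa (1.13 at T9), Cmpk2 (-1.82 at T2.5), Ifit1 (-1.48 at T2.5), Ifit2 (-1.29 at T2.5), Phlda1 (1.81 at T6) and Rsad2 (-1.67 at T13). All share the untreated libraries, and 8 of the 10, the exceptions being Csf3 and Pdgfa, passed between genotypes at T0 with the opposite sign.

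The first pattern is the 354 genes lower in Cop1-floxed cells at 3 or more LPS times, Col1a1 and Postn among them. A scaling factor moves all genes of a library alike. The median of all genes moved by at most 0.19 on the log2 scale between the 3 scalings at any LPS time. Tested against that shift with p-values adjusted over all tested genes, 46.9% of the 354 passed at 3 or more LPS times. For single genes among the others a part of scaling stays open. Over the set, the median fold was -1.57 with TMM, -1.59 with the size factors of DESeq2 and -1.69 with library totals. The test argues against scaling as the source of the fall for the 46.9% that passed it. The median fall of the set is large beside its median SE of 0.361. The genes were picked by their calls, so that fall can be overstated and does not decide for the rest. Fewer stromal cells in the Cop1-floxed cultures is a candidate explanation. After removing group means, the 345 genes outside the stromal list had a median correlation of 0.74 with the stromal list score over the libraries. In 1000 random gene sets it was at most 0.096. The median was 0.88 in the wild-type and 0.63 in the Cop1-floxed libraries. The libraries come from 6 mice, and wild-type replicate 1 and Cop1-floxed replicate 2 had the lowest score of their genotype at every time. Deviations of a mouse thus count more than once, which the random sets do not measure. With that score as a covariate 3.39% of the 354 were still called lower, their median fold going from -1.57 (median SE 0.361) to -0.12 (0.301), but only 26.1% of the 261 genes of the third pattern kept their call as well, with medians of 0.41 (0.103) and 0.35 (0.137), so a lost call is not specific to the 354. At every time the score was lower in every Cop1-floxed library than in every wild-type library (at T6 at most 3.46 against at least 4.09). Of the 354 genes, 9 are members of the score. Such a covariate takes up much of any genotype difference by construction, so this fit does not decide. The abundant stromal genes Col1a1 and Col1a2 had 226 and 233 CPM in wild-type and 39.7 and 51.8 CPM in Cop1-floxed cells at T6, none of the 14 markers is held by another list, and a direct effect of Cop1 on these genes was not tested and stays open.

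The second pattern is the higher level of LPS-induced genes in untreated Cop1-floxed cells. It was taken over 182 genes that LPS induced at least 32-fold in wild-type cells at 1 or more times. They also had a mean of at least 100 CPM in Cop1-floxed cells at 1 or more LPS times, so induced genes at lower levels were left out. Of these 182 genes, 169 were higher in untreated Cop1-floxed cells and 113 passed. Carry-over of LPS-treated material might raise each by 1 common share of its LPS level. At the best fitting time, T6, 61.5% lay within 2-fold of the median share of 0.406%, so for these genes carry-over and a mild activation of the cells cannot be told apart, as both raise the genes that LPS induces. For the 631 genes called higher that LPS induced under 10-fold, carry-over stays open too: tested against what the largest median share of the 5 LPS times, 1.3% at T2.5, would give, with p-values adjusted over all 14344 such genes, 50.4% lay above it, but with library totals only 76 genes did, as their median fold fell from 0.43 (median SE 0.106) to 0.31 (0.111), against a median of 0.041 and at most 0.17 that carry-over would give; these folds are of genes picked by their call at T0, so the medians alone do not decide. A few activated cells in these cultures and an effect of the genotype itself were not tested and stay open.

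The third pattern is the 261 genes higher in Cop1-floxed cells at 3 or more LPS times, with a median of 0.41. Whether scaling accounts for these calls stays open. Against the shift of 0.19, the largest at any LPS time, 8.81% passed the test at 3 or more LPS times. With a median SE of 0.103, a median of 0.41 lies so close to that shift that few genes could pass whatever the cause. This share therefore does not decide. With library totals 32.6% were still called higher and the median fell to 0.29 (median SE 0.109, against 0.103). The size factors of DESeq2 kept 77.0%. Library totals move the median of all genes down at every LPS time, at T9 from 0.025 to -0.15. A loss of higher calls with them was therefore fixed by the direction of the shift and does not decide. Granulocytes in the cultures remain undecided: the 17 granulocyte markers outside the pattern had a median of -0.0747 with an SD of 1.12. The 2 markers in the pattern, Mmp8 (0.94) and Ltf (0.79), were left out, which lowers that median. Markers also went both ways, from -2.68 for Mpo to 1.66 for Retnlg, several of them under 1 CPM, so the median decides little. Under LPS wild-type and Cop1-floxed cells had 239 and 309 CPM of Csf3r, the most abundant of the 17, and 22.8 and 25.8 of S100a9. They had 17.2 and 23.4 CPM of S100a8 and 4.70 and 0.70 of Mpo. Of the 20 listed markers, 6 are also held by another list. Fewer stromal cells remain undecided too, since the median correlation with the stromal score was -0.11, against a median of -0.13 in random sets. By genotype it was 0.024 in the wild-type and -0.36 in the Cop1-floxed libraries. An effect of the genotype on these genes was not tested and stays open.

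The 10 splits of 3 against 3 are too few for a share under 0.05. For the genotype difference, the real split gave 1501 genes at T0, with 18 as the highest other, 612 at T2.5 with 0, 763 at T4 with 0, 1224 at T6 with 4, 1639 at T9 with 9 and 486 at T13 with 0. At an unadjusted p under 0.05 edgeR gave 3336, 2228, 2650, 3239, 3778 and 1945 genes from T0 to T13 in the real split, and at most 3385, 540, 891, 994, 1689 and 420 in another, so at T0 another split gave more than the real one. The real split gave 1259 genes summed over times and 94 for the interaction, each with 0 as the highest other (at an unadjusted p under 0.05, 3463 and 1192, with 1044 and 540). By adjusted p, each of these was the 1 split of 10 with a count as large.

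For LPS against T0, fitted on 6 libraries, the real split gave 7019, 8323, 8809, 8857 and 8467 genes in wild-type cells from T2.5 to T13 and 9571, 10579, 11037, 10211 and 10642 in Cop1-floxed cells. The highest other was 0 in edgeR in each case, with at most 773 genes at an unadjusted p under 0.05. Every other split mixes untreated and LPS libraries in both groups, so the wide LPS response becomes spread within the groups. Few or no calls there were largely fixed by the design, so this contrast does not measure chance. Of the 10 splits, 4 part all 3 pairs of libraries from the same mouse, as the real one does; the others keep 2 pairs together. For the gene lists, the real split of the genotypes gave 12 calls at T0 (highest other 8), 8 at T2.5 (11, with 3 splits as large), 6 at T4 (12, with 4), 12 at T6 (9), 12 at T9 (7) and 8 at T13 (9, with 3). For LPS in wild-type cells it gave 9, 9, 9, 10 and 11 list calls, with highest others of 12, 14, 13, 11 and 13, and 9, 7, 6, 4 and 7 of the 10 splits were as large. The other splits hold untreated and LPS libraries in unequal numbers in each group, so a part of the LPS response stays in them. These list counts therefore cannot show whether the LPS list calls exceed chance.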

How the results depend on the processing

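The library totals, the single libraries left out, the stromal covariate and the T0 set of weakly induced genes were chosen only after the results were seen; all other alternatives were planned.

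Of the values of named genes under the alternatives, 2296 kept their direction and side of the threshold, 215 were no longer past it (1 of them, Tnn, with no adjusted p in DESeq2), 9 newly passed and 31 changed sign, 26 of these for genes that passed neither before nor after. Of the counts and Cop1 values, 466 stayed within 1.5 times or on their side, 73 were lower and 16 higher. The counts for LPS in either genotype moved past 1.5 times only with the filter at 5 CPM, which leaves fewer genes to test. Cop1 changed its call only at T0, in the fits of 6 libraries. Genes under about 5 CPM and differences under 2-fold are the least certain at 3 mice per group. Except where fewer genes or samples entered, the cause of each change was not tested.

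With an estimated correlation the list calls for the genotype were 1 at T0, T2.5, T4 and T13 and 0 at T6 and T9, where 6 and 8 lists had an unadjusted p under 0.05 and camera and fry called 12 and 12, and 10 and 12; for LPS in wild-type cells they were 5 at T4 and T6 and 6 at T13. Fry, which tests lists on their own and not against other genes, called 3 lists at T2.5 for the genotype and 23, 24, 25, 22 and 23 for LPS in wild-type cells. Without a filter the interaction had 158 genes. With a mean of at least 5 CPM the genotype counts were 812 at T0, 266 at T2.5, 320 at T4, 607 at T6, 876 at T9 and 420 summed, and those for LPS 6915 at T13 in wild-type cells and 7306, 7329 and 6789 at T6, T9 and T13 in Cop1-floxed cells. Without the library Cop1-floxed T9 replicate 2 there were 783 genes at T9 and 5 lists at T2.5. Without wild type T0 replicate 2 there were 939 genes at T2.5, 1227 at T4 and 1894 at T6. The 6 libraries of a time alone gave 9 genes at T0, with Cop1 at -0.76, and 563 at T9. The mean contrast over all 36 libraries gave 4919 genes in place of the summed count; it treats the 6 libraries of a mouse as separate samples.

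With the stromal list score as a covariate the counts were 276 at T0, 169 at T2.5 and 617 at T6. That score separates the genotypes at every time, so the covariate takes up a part of the genotype difference by construction. That covariate turned the sign of Col2a1 (0.12 at T0, 0.048 at T9), Dkk3 (0.57 at T0, 0.50 at T9) and Lrrc32 (0.082 at T9), and of the uncalled Jun (0.14 at T0), Etv5 (0.11 at T9), Il1b (0.12 at T9), Tnf (-0.075 at T9) and Ptgs2 (-0.48 at T9). With library totals Tnf (-0.029 at T9), Ptgs2 (-0.028 at T9) and Arg1 (-0.086 at T0) changed sign. Arg1, at 0.031 at T0, was also at -0.048 with the filter at 5 CPM, -0.064 in the 6 libraries alone, -0.088 with a block for the replicate number, -0.023 in limma-trend and -0.035 in DESeq2. Without the library Cop1-floxed T9 replicate 2 Il6 (0.012 at T9) and Ifnb1 (0.025 at T9) turned, and without wild type T0 replicate 2 Cebpb did (0.055 at T0). Limma-trend on the RPKM values gave 399 genes at T2.5 and 735 summed. DESeq2 gave 751 at T13, 2057 summed and 320 for the interaction, where 2132 genes had no adjusted p.

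Leaving out each mouse in turn gave 642 to 2401 genes at T0, 134 to 822 at T2.5, 237 to 926 at T4, 470 to 1387 at T6, 678 to 1794 at T9 and 97 to 659 at T13. It gave 51 to 1841 summed, 14 to 72 for the interaction, and 5 to 12 lists at T2.5 and 3 to 10 at T4. Uncalled genes that changed sign ranged from -0.61 to 0.54 for Arg1, -0.19 to 0.051 for Jun and -0.37 to 0.024 for Cebpb at T0, and from -0.34 to 0.0090 for Etv5, -0.044 to 0.29 for Tnf, -0.46 to 0.019 for Il6 and -0.36 to 0.18 for Ifnb1 at T9. The highest gene counts came without wild-type replicate 1 and the highest of these 2 list counts without Cop1-floxed replicate 1, and the arm with a mouse left out keeps 2.

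With the individual as a block, which the labels give for LPS against T0, the interaction had 335 genes. The counts for LPS stayed within 1.5 times, and the 50 values of named genes followed under this block kept their call. Whether other genes kept theirs was not compared. Across genotypes the libraries share only a number: the 18 same-number pairs correlated at -0.176 to 0.117 (median -0.0782, 1 over 0.1), and 4 of 18 libraries correlated best with their own number. A block for that number gave 180 genes summed, 0 at T0 in edgeR (1289 at an unadjusted p under 0.05), with Cop1 at -0.76, 451 at T4, 586 at T6 and 73 at T9.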

Other observations

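No test of an explanation is reported here; the sex-linked genes were listed beforehand, and the values of the single library given last were chosen only after the result was seen.

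Wild-type replicate 2 stood apart in its sex-linked genes. Its 6 libraries had 25.6 to 89.8 CPM of Xist, the RNA that silences an X chromosome in female cells, against at most 0.90 CPM in the libraries of the other 5 mice. They also had reads of Y-linked genes, with a mean of 22.1 CPM for Ddx3y, against means of 42.2 to 53.2 CPM in the other mice, and 21.6 CPM for Eif2s3y, where wild-type replicate 3 had 17.8 CPM. The labels give these libraries as 1 individual, and they were counted as 1; whether they hold RNA of more than 1 mouse was not given in the sources used here. Without this replicate the genotype effect at T0 had 851 genes and that at T6 778. Of the genes called with it and tested in both fits, 724 of 1499 kept their call at T0. At T2.5 and T4, 288 of 612 and 477 of 759 did. At T6, T9 and T13 it was 688 of 1224, 1019 of 1633 and 268 of 485.

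The response to LPS was wide. In wild-type cells 14250 of the 15685 tested genes passed at 1 or more of the 5 LPS times, 2764 were higher and 2335 lower at all 5, and 1779 were higher at some times and lower at others. In Cop1-floxed cells 14243 genes passed at 1 or more times. Between genotypes under LPS, 2431 genes passed at 1 or more times, and 1 gene did so in both directions.

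The library Cop1-floxed T9 replicate 2, which detected 15045 genes, had a score of -64.7 on the fourth principal component, which held 5.31% of the variance.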
